A study of Homo sapiens with 6 samples.

How the data were processed

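Gene expression was measured by RNA-seq in 6 samples of the human iPS line ChiPSC12-M, in 2 groups of 3 labelled biological replicates, untreated and treated with Tet-Express for 4 h in Day 1 endoderm differentiation medium. Per the labels' protocols, stable transfectants were selected with 0.2 μg/ml and kept in 0.1 μg/ml puromycin, and stranded mRNA libraries were made from 1 μg of total RNA. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, Bowtie2, RSEM and edgeR and the genome build hg19. The role of each tool, the annotation and any filters are not given in the sources used here. How strand was used in counting is likewise not given, so overlapping and antisense genes may share reads.

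The deposited values are a scaled signal, gene counts normalised per library by the authors, with 1 column per sample and 0 columns of other samples. Their sums lay between 936717 and 1145468 per library, so they are not plain shares of the reads. In each column every value was a whole multiple of the smallest one, with 100% of values whole within 0.001, so whole reads were recovered for each gene. Recovered reads numbered 25272043, 22398304 and 18040536 in untreated libraries 1, 2 and 3 and 31036125, 25900300 and 18469509 in Tet-Express libraries 1, 2 and 3. The floor of 3 reads corresponds to deposited values of 0.0906 to 0.168. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. RSEM divides reads among similar transcripts, so genes with near-identical copies and read-through models have uncertain values.

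The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trended prior variance and no covariate, two-sided, with Benjamini-Hochberg adjustment. Genes with a value of at least 1 in at least 3 of the 6 libraries were tested (13998 of 19961). A fold change on the log2(value + 1) scale understates changes of low genes. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists, and again with an estimated correlation and with fry. The 36 lists cover respiration, oxidative and other stress responses, signalling, cell cycle, developmental states and markers of other cell types. They were fixed before the data were examined, as were the main design and the alternatives named below unless said otherwise. On simulated data drawn with the spread of these libraries (14025 genes), limma recovered 2 of 67 genes changed 1.5-fold, 21 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 9 calls among unchanged genes. With a spread of 10 percent between replicates it recovered 60 of 67, 67 of 67 and 66 of 66. The replicate spread thus limits what is detectable at this size. A simulated raised list gave a camera p of 2.972e-16 and an unchanged one 0.491. Simulated genes were drawn independently, with no difference between batches or whole libraries. Recovery in the real libraries, which hold such differences, may therefore be lower than simulated. The check also does not cover lists whose genes move together. The estimated correlation in the real data was 0.90 for ribosomal proteins and 0.71 for the respiratory chain list.

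The genes named in the text follow a fixed rule. SDHC comes first. Next come the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5, passing over names of unnamed loci. Places left go to the genes with the smallest unadjusted p in that direction, said not to have passed, and this filled every place here. Then come up to 4 members with the smallest p per described list, and SDHA, SDHB, SDHD, POU5F1, SOX2, KLF4 and MYC. Genes named outside the rule were chosen after their values were seen.

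Alternatives were another scaling of the values (median of ratios or quantiles), no filter or a filter at 50, pseudocounts of 0.5 and 10, other prior variances, library weights, the replicate number as a block, each library left out, and edgeR 4.0.16 on the recovered reads. A threshold of 0.1, or a log2 change of at least 1 beside 0.05, changes no count, as no adjusted p came near. A batch term, that term without Tet-Express library 2, a fit of libraries 2 and 3 alone, DESeq2 1.42.0 and edgeR with a block or with the batch term were added after seeing the data. The batch is libraries numbered 1 against those numbered 2 and 3, and is not given in the labels. The principal components set the libraries numbered 1 apart from untreated 2, untreated 3 and Tet-Express 3. Tet-Express 2 lay with neither, so it was placed by its number alone and its within-batch values rest on that. The scalings moved the median of all genes by less than 0.1 on the log2 scale.

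The reference used here is GENCODE v29 on GRCh38, a different build from the authors', so no coordinates are given. It served for transcript length and GC content, taken from the principal transcript of each gene and matched for 13733 of the tested genes (98.1%), and for matching older gene symbols together with tables of gene names. XIST and Y-linked genes were not named or plotted. An SE given for a list median comes from resampling the list's genes within each difference between libraries. Genes of a list can move together, so that SE can be too small, and it does not measure variation between cultures. Raw reads were not analysed here.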

Results

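RNA-seq gene values were collected from ChiPSC12-M, a human induced pluripotent stem (iPS) cell line made from ChiPSC12 by stable transfection with a vector carrying SDHC (I69E). SDHC encodes a membrane anchor subunit of succinate dehydrogenase, complex II of the respiratory chain. Cells in endoderm differentiation medium were given Day 1 medium for 4 h, either without further addition (untreated, n = 3) or with Tet-Express, a transcriptional activator protein (n = 3). The samples are labelled as biological replicates, with no statement of which cultures were grown or sequenced together. The series concerns control of reactive oxygen species (ROS) in iPS cells and early steps of tumour formation, and the single comparison its design gives is Tet-Express against untreated. The table held 19961 genes, and whole reads recovered from the values numbered 18040536 to 31036125 per library. Between 18246 and 19314 genes had at least 1 read in a library, and the 10 most abundant genes took 6.20% to 6.53% of the reads.

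SDHC, the gene carried by the vector, was 113 in untreated library 1, 88.0 in untreated library 2 and 90.5 in untreated library 3. It was 123 in Tet-Express library 1, 116 in Tet-Express library 2 and 96.2 in Tet-Express library 3. The means were 97.2 ± 13.9 untreated and 112 ± 13.7 with Tet-Express (SD, n = 3 each), in the deposited scaled values. The log2 difference on the log2(value + 1) scale was 0.20 with an SE of 0.17 and a 95% confidence interval of -0.20 to 0.60. As a fold, the interval runs from 0.872 to 1.51. SDHC therefore did not differ by more than the spread between replicates (limma adjusted p = 0.998; two-sided exact permutation p = 0.2, where 3 against 3 cannot go below 0.1). Against untreated libraries of the same batch, described in the next paragraphs, SDHC was higher by 0.11 in Tet-Express library 1, 0.37 in library 2 and 0.11 in library 3. The table has 1 SDHC row and does not separate vector from endogenous transcripts. The catalytic subunit SDHA (log2 difference -0.04), the iron-sulfur subunit SDHB (0.18) and the second anchor subunit SDHD (-0.03) also did not pass (adjusted p = 0.998 each). The list of 8 SDH subunits and assembly factors had a median of 0.15 and did not pass camera, limma's gene set test (adjusted p = 0.338).

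**Figure D1:**
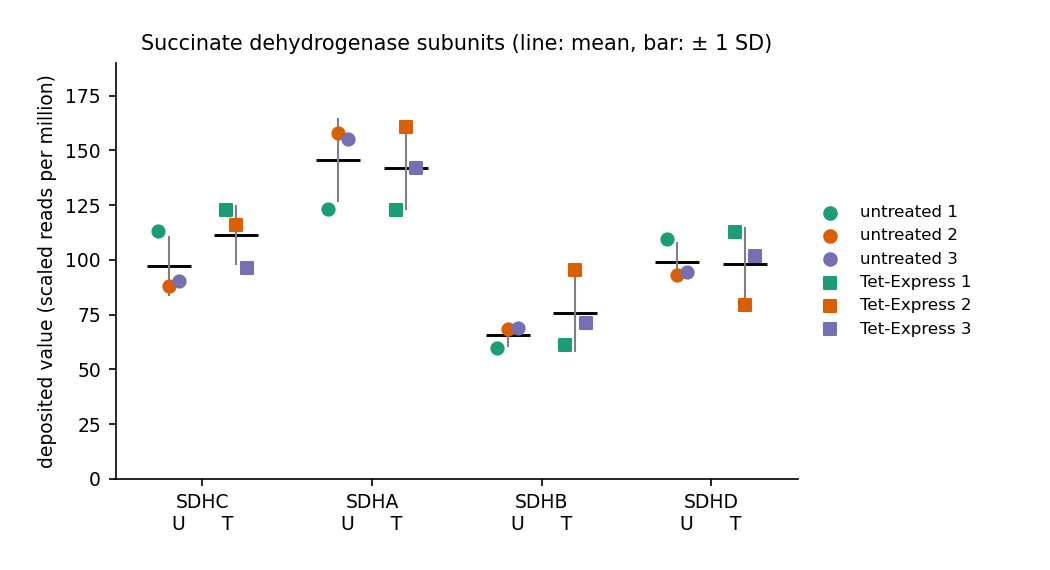
Deposited values (scaled reads) of the 4 succinate dehydrogenase subunits in each library; circles are untreated (U), squares Tet-Express (T), colours the replicate numbers, lines the group means and bars 1 SD. For SDHC, Tet-Express library 3 (96.2) lies below untreated library 1 (113), so the groups overlap.

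No single gene passed the test between Tet-Express and untreated cultures. Of 13998 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.998. At an unadjusted p under 0.05 there were 68 genes (22 higher and 46 lower), where chance would give 699.9. That low count belongs to a model without the batch described below. With a batch term in limma it was 241, and with Tet-Express 2 also left out 1779 of 13884 genes (1187 higher). The count thus depends on how the spread between libraries is modelled, and both fits were chosen after the result was seen. In 418 genes all treated values lay above all untreated ones and in 266 all lay below, together 4.89% against 10% by chance. edgeR's quasi-likelihood test on the recovered reads gave 0 higher and 0 lower with 88 genes at an unadjusted p under 0.05. DESeq2 on the same reads gave 3 higher and 8 lower, all named below. The largest spread between libraries did not follow the treatment. The first principal component (48.2% of variance) and the second (42.1%) set libraries numbered 1 of both groups together, untreated 2, untreated 3 and Tet-Express 3 together, and Tet-Express 2 apart from all others. Across genes, log2 values correlated at r = 0.998 between untreated 1 and Tet-Express 1 and at r = 0.997 between untreated 2 and untreated 3. These closest pairs still differed by more than sampling noise, with median chi-square ratios to expectation of 1.44 and 1.35, and were counted separately. Values are therefore also given within a batch, where Tet-Express 2 is placed by its number alone, as Tet-Express 1 minus untreated 1, and as Tet-Express 2 or 3 minus the mean of untreated 2 and 3.

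**Figure D2:**
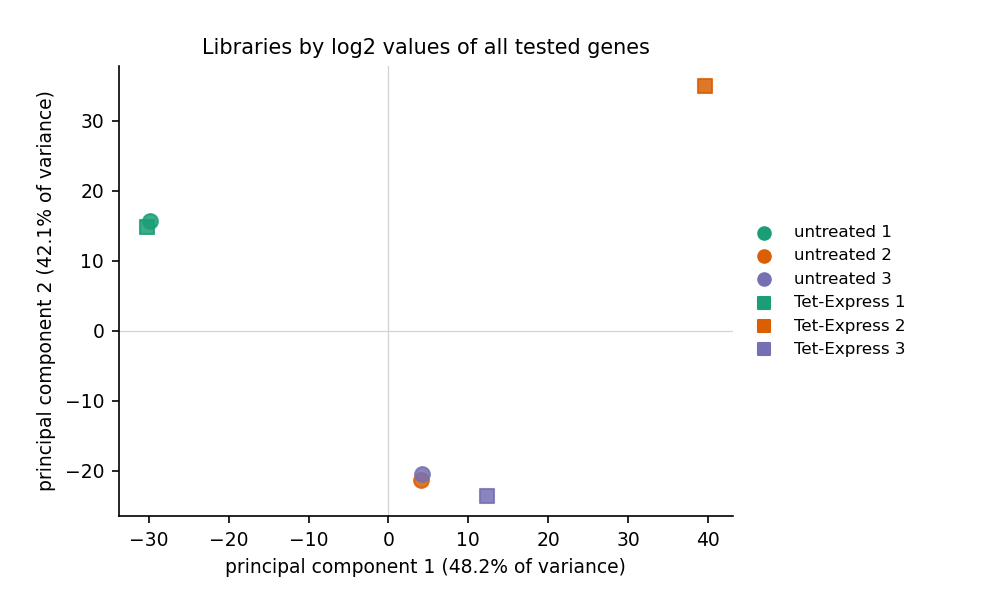
Principal components 1 and 2 of the log2 values of all tested genes, with 1 point per library; circles are untreated, squares Tet-Express and colours the replicate numbers. Both libraries numbered 1 lie together on the left, and Tet-Express 2 lies alone at the top right.

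The 10 genes with the smallest unadjusted p among those higher with Tet-Express did not pass, and 2 of them, NR4A1 and ATF3, are in the fixed list of immediate early genes. NR4A1, an orphan nuclear receptor, had values of 24.6, 20.4 and 20.3 untreated and 26.0, 47.7 and 41.3 with Tet-Express (log2 difference 0.75, SE 0.24, unadjusted p = 0.0141). ATF3, a stress-induced transcription factor, had 50.4, 45.2 and 43.2 against 53.9, 82.4 and 83.8 (0.63, SE 0.21). MAFF, a small MAF transcription factor, had 11.2, 9.20 and 11.1 against 11.5, 20.5 and 22.4 (0.69, SE 0.26). PPP1R15A, the stress-inducible phosphatase subunit acting on eIF2-alpha, differed by 0.52. RGS2, a regulator of G protein signalling, differed by 0.50 and the phosphatase DUSP8 by 0.48. DPM3, a subunit of dolichol-phosphate-mannose synthase, differed by 0.83, SCHIP1 by 0.64, PNRC1 by 0.51 and the small heat shock protein HSPB8 by 0.67. All 10 had an adjusted p of 0.998 in limma. Within batches the differences lay mostly in libraries 2 and 3. NR4A1 was 0.07 in Tet-Express 1, 1.19 in Tet-Express 2 and 0.99 in Tet-Express 3, and ATF3 was 0.09, 0.88 and 0.91. SCHIP1 was higher in each treated library, by 0.40, 0.61 and 0.92.

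The 10 genes with the smallest unadjusted p among those lower with Tet-Express also had an adjusted p of 0.998 each. RGPD6, of a family of RANBP2-like genes, had values of 7.82, 10.2 and 8.29 untreated and 0.694, 1.86 and 4.25 with Tet-Express (log2 difference -1.73, SE 0.38, unadjusted p = 0.0016). Its within-batch differences were -2.38, -1.84 and -0.96. POTEE (-0.90), POTEF (-0.71), FAM45A (-0.82) and the read-through model BIVM-ERCC5 (-1.47) were also in this set. RGPD6, POTEE, POTEF, FAM45A and BIVM-ERCC5 have near-identical copies or overlapping gene models that share reads, so their values are uncertain. PLCG2, a phospholipase, differed by -0.72 and BSN, a presynaptic scaffold gene, by -0.65. Within batches these differences lay in Tet-Express 2 and 3. PLCG2 was -0.05, -1.17 and -0.94 in Tet-Express 1, 2 and 3, and BSN was -0.001, -1.15 and -0.78. The remaining 3 genes encode proteins secreted by liver, namely transferrin (TF, -1.79), complement C3 (C3, -1.09) and apolipoprotein B (APOB, -1.60). TF was 1.19, 10.7 and 10.2 in the untreated libraries and 0.916 ± 0.203 in the treated ones (SD, n = 3). Without untreated library 1, TF passed (log2 difference -2.59, limma adjusted p = 0.0367; its adjusted p lay between 0.323 and 1.00 under every other limma setting, and DESeq2 called it, as given below).

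Liver transcripts stood apart in untreated libraries 2 and 3. Albumin (ALB) was 71.6 (1627 reads) in untreated library 2 and 124 (2287 reads) in untreated library 3, but had 0 reads in untreated library 1 and in Tet-Express library 1, 10 in Tet-Express library 2 and 4 in Tet-Express library 3. Against the floor of 3 reads in untreated library 1, ALB was at least 644-fold higher in untreated library 2, counting error only. ALB reached a value of 1 in too few libraries to be tested. Haptoglobin (HP) was 9.81 and 10.1 in untreated 2 and 3 and at most 0.181 elsewhere. SERPINA1 was 2.77 and 7.37, and at most 0.224 elsewhere. Among the 8 genes that DESeq2 called lower, 7 are liver transcripts (A2M, HPX, ORM1, PLG, SERPINA1, TF and TTR) and the other is the read-through model RAB4B-EGLN2. The 3 it called higher were the read-through models CORO7-PAM16 and MINOS1-NBL1 and the pseudogene NUDT4P1. These genes were named after their values were seen.

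**Figure D3:**
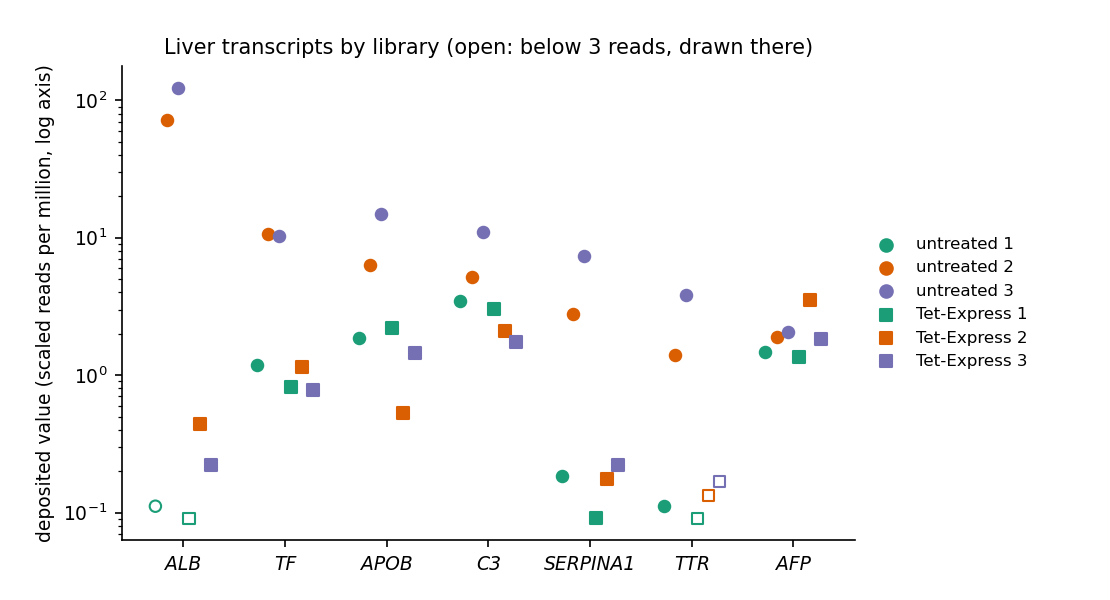
Deposited values (scaled reads, log axis) of liver transcripts in each library; circles are untreated, squares Tet-Express, colours the replicate numbers, and open symbols mark values below 3 reads drawn at that floor. ALB is 71.6 and 124 in untreated libraries 2 and 3 and at most 0.442 elsewhere, while AFP (1.36 to 3.54) shows no such gap.

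Of 36 gene lists fixed in advance, 35 could be tested, and 9 were higher with Tet-Express as groups by camera with a preset correlation of 0.01. With an estimated correlation 0 of the 9 passed (smallest adjusted p = 0.704), and fry, which tests whether a list moves one way on balance, also gave 0 (smallest adjusted p = 0.789). No list had a member past the threshold over all genes or when adjusted over the list alone, where the smallest p was 0.155. With a term for the batch and Tet-Express 2 left out, 2 of the 9 passed at the preset correlation, ribosomal proteins and immediate early genes. The other 7 had adjusted p between 0.125 and 0.402. Ribosomal proteins and immediate early genes showed no rise in Tet-Express 1 (medians -0.01 and -0.03). Their calls in that fit thus rest on Tet-Express 3 alone (0.15 and 0.56).

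Protein synthesis and respiratory chain transcripts made up the largest of these groups. All 68 ribosomal protein genes had positive differences, with a median of 0.37 (adjusted p = 5.11e-20, and adjusted p = 0.704 with an estimated correlation). RPL9 was 699 ± 138 untreated and 1042 ± 370 with Tet-Express (SD, n = 3 each), and RPS25 was 342 ± 43.3 and 469 ± 126. Of 73 nuclear-encoded subunits of respiratory complexes I, III, IV and V, 72 had positive differences, with a median of 0.29 (adjusted p = 5.15e-14, and adjusted p = 0.704 with an estimated correlation). Examples were ATP5L (log2 difference 0.41) and NDUFC2 (0.47). The size came from Tet-Express 2. There the ribosomal median was 0.95 and the respiratory chain median 0.79, against -0.01 and -0.01 in Tet-Express 1 and 0.15 and 0.08 in Tet-Express 3. Without Tet-Express 2 both lists still passed at the preset correlation (adjusted p = 4.22e-05 and 0.0222; the estimated correlation was not run there), but with a term for the batch as well the respiratory chain list did not (0.188). In Tet-Express 2 the difference fell with transcript length across all genes, from a median of 0.68 in the tenth of genes with the shortest transcripts to -0.54 in the tenth with the longest.

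Genes that handle reactive oxygen, metals and sugar were higher as lists but not as genes. Among 25 ROS-detoxifying enzymes 21 had positive differences and the median was 0.28 (adjusted p = 7.69e-04, and adjusted p = 0.704 with an estimated correlation). PRDX1, a peroxiredoxin, was 790 ± 54.1 untreated and 1011 ± 240 with Tet-Express (SD, n = 3 each), and GLRX5 differed by 0.30 on the log2 scale. The 10 tested metallothionein list members, which bind metals, had a median of 0.36 with 9 positive (adjusted p = 0.0114, and adjusted p = 0.704 with an estimated correlation), with MT1G at 0.38 and MT1F at 0.34. Of 17 glycolysis enzymes 14 were positive, with a median of 0.17 (adjusted p = 0.0436, and adjusted p = 0.841 with an estimated correlation), ENO1 at 0.31 and TPI1 at 0.32. The within-batch medians in Tet-Express 1, 2 and 3 were -0.01, 0.66 and 0.10 for ROS enzymes, 0.02, 0.91 and 0.04 for metallothioneins and 0.01, 0.41 and 0.07 for glycolysis. Without Tet-Express 2 all 3 lists lost their call (adjusted p = 0.107, 0.497 and 0.775). After the length trend of Tet-Express 2 was removed, its medians were 0.25 ± 0.14 for ROS enzymes and 0.22 ± 0.06 for metallothioneins (SE over the list's genes). Metallothioneins also lost their call with the filter at 50 (0.0850). Glycolysis also lost it without untreated 1 (0.339) or Tet-Express 3 (0.223), with quantile normalization (0.9395), with the filter at 50 (0.181) and with a pseudocount of 0.5 (0.0502). The lists of NRF2 targets (median 0.14, adjusted p = 0.225), which respond to oxidative stress, and of HIF targets (0.09, adjusted p = 0.155), which respond to low oxygen or succinate, did not pass. Without Tet-Express 2 the HIF list passed at the preset correlation (adjusted p = 0.00263, or 0.0252 with a term for the batch). With all libraries it had an adjusted p = 0.704 with an estimated correlation, which was not run without Tet-Express 2. FTL of the NRF2 list differed by 0.48 and NQO1 by 0.37, and ADM of the HIF list by 0.70 and BHLHE40 by 0.52, none past the threshold.

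Immediate early genes, which are transcribed within minutes of a stimulus, had positive differences in 24 of 26 tested members, with a median of 0.31 (adjusted p = 1.25e-07, and adjusted p = 0.704 with an estimated correlation). NR4A1 and ATF3, given above, had the smallest p among them. The within-batch medians were -0.03 in Tet-Express 1, 0.35 in Tet-Express 2 and 0.56 in Tet-Express 3, and the list passed at the preset correlation without any one library. Removing the trend on GC content in Tet-Express 2 left 0.13 ± 0.13 (SE over the list's genes), and untreated 1 exceeded untreated 2 and 3 by a median of 0.67. The ATF4 and integrated stress response list had 18 of 23 members positive and a median of 0.20 (adjusted p = 0.0226, and adjusted p = 0.704 with an estimated correlation), led by ATF3 and by ATF4 (log2 difference 0.43). Its medians were 0.00, 0.35 and 0.14 in Tet-Express 1, 2 and 3. It lost its call without untreated 2 (adjusted p = 0.128), untreated 3 (0.131), Tet-Express 1 (0.208) or Tet-Express 3 (0.0746), with quantile normalization (0.220) and with the filter at 50 (0.102).

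**Figure D4:**
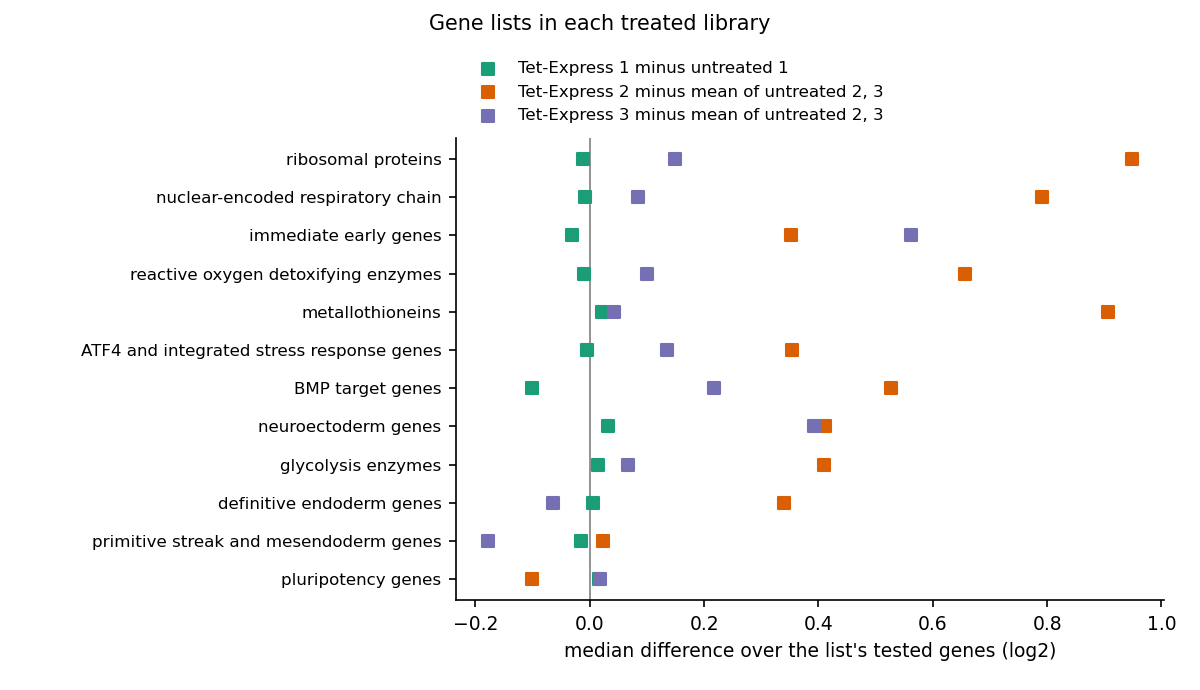
Median log2 difference over the tested members of each gene list (horizontal axis), for each treated library against the untreated libraries of its batch; the first 9 lists are those past camera's preset-correlation test. Ribosomal proteins stand at -0.01, 0.95 and 0.15 in Tet-Express 1, 2 and 3 and immediate early genes at -0.03, 0.35 and 0.56.

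The pluripotency, primitive streak and definitive endoderm lists did not pass. The cultures expressed pluripotency genes and early primitive streak genes together: POU5F1, which encodes OCT4, was 1697 ± 335 untreated and 2238 ± 676 with Tet-Express (SD, n = 3 each), and T (brachyury) was 79.4 ± 34.7 and 71.0 ± 26.4. The endoderm gene SOX17 stayed between 0.559 and 1.11. The 25 pluripotency genes had a median of 0.01 with 13 positive (adjusted p = 0.733), while TRIM71 was 431, 369 and 352 untreated and 410, 113 and 317 with Tet-Express. The 17 primitive streak genes had a median of -0.03 (adjusted p = 0.723), with WNT8A at -0.44 and FGF4 at -0.41. The 9 definitive endoderm genes had a median of 0.06 (adjusted p = 0.383), with CLDN6 at 0.33 and CXCR4 at 0.40. The reprogramming factor genes SOX2 (log2 difference 0.01), KLF4 (0.17), MYC (0.18) and POU5F1 (0.37) did not pass. Among developmental lists the BMP target list (median 0.22, 9 of 11 positive, adjusted p = 0.0424, and adjusted p = 0.704 with an estimated correlation) and the neuroectoderm list (0.30, 7 of 8 positive, adjusted p = 0.0436, and adjusted p = 0.704 with an estimated correlation) passed. BAMBI (0.27) and GATA2 (0.34) had the smallest p in the BMP list, SOX3 (0.59) and HESX1 (0.34) in the neuroectoderm list. Within batches the BMP medians were -0.10, 0.53 and 0.22 in Tet-Express 1, 2 and 3, and the neuroectoderm medians 0.03, 0.41 and 0.39. The BMP list lost its call without untreated 2 (adjusted p = 0.137), untreated 3 (0.0925), Tet-Express 2 (0.117) or Tet-Express 3 (0.379), with quantile normalization (0.0565), with the filter at 50 (0.216) and with the replicate number as a block (0.0656). The neuroectoderm list lost it without untreated 1 (0.190), untreated 3 (0.0640), Tet-Express 2 (0.148) or Tet-Express 3 (0.379), with no filter (0.0980) and with a pseudocount of 10 (0.176). The 26 lists that did not pass had adjusted p between 0.0785 and 0.946, and the list of mitochondrially encoded transcripts had 0 members in the table.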

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

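The batch term, that term with Tet-Express library 2 left out, the fit of libraries 2 and 3 alone, DESeq2, and edgeR with a block or batch were chosen after the result was seen. The count of genes higher with Tet-Express was 0 under every setting chosen before. It was 3 with DESeq2, 1 with edgeR and the replicate block and 1 with edgeR, the batch term and Tet-Express library 2 left out. Genes lower numbered 0 to 1 when 1 replicate was left out (1, TF, without untreated replicate 1), 1 with the batch term and Tet-Express library 2 left out, 8 with DESeq2 and 3 with edgeR in that batch fit. The genes called are liver transcripts, read-through models and a pseudogene. The SDHC difference stayed positive, between 0.10 and 0.31, with adjusted p between 0.369 and 1.00. Gene lists past the threshold numbered 5 to 11 with 1 replicate left out, 4 with the filter at 50, where fewer genes are tested, 3 with the batch term and Tet-Express library 2 left out, 0 with an estimated correlation and 0 with fry. Except where the filter or fewer samples account for it, the cause was not tested.

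Replicate numbers did not pair all the samples. Deviations from the group means correlated at 0.718, 0.0531 and 0.588 for numbers 1, 2 and 3. Across the groups the libraries numbered 1 correlated best with each other, but not every sample correlated best with its own number. With the replicate block limma gave 0 genes higher, 0 lower (237 at an unadjusted p under 0.05) and 9 lists, and SDHC stayed at 0.20.

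Among named genes 927 values kept their direction and side, 1 became stronger (TF) and 13 changed sign, all with small differences that did not pass. With 1 replicate left out, SDHA ranged from -0.15 to 0.0618, SDHD from -0.14 to 0.12, SOX2 from -0.25 to 0.32 and KLF4 from -0.0510 to 0.37. SDHD was 0.12 with library weights and 0.0834 with the batch term and Tet-Express library 2 left out. SOX2 was -0.0433 with quantile normalization and -0.18 with library weights. Of list medians 156 kept within their spread and 12 moved. Their cause was not tested.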

Other observations

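The tests of AFP, of untreated 1 against Tet-Express 1, of changes shared by all treated libraries, of untreated libraries against each other and of length and GC content for immediate early genes, the Fisher and ratio tests and the batch term were chosen after the result was seen, as was the use of principal rather than longest transcripts.

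The cholesterol synthesis, p53 target and ribosome biogenesis lists differed between libraries numbered 1 and others both without Tet-Express and with it, where Tet-Express 3 was compared. The immediate early and primitive streak lists, also given here, did not differ clearly in both. Of 26 immediate early genes 15 were higher and 3 lower in libraries 1 in both comparisons (medians 0.67 and 0.09). All 22 cholesterol synthesis genes were lower in untreated 1 than in untreated 2 and 3 and lower in Tet-Express 1 than in Tet-Express 3, with medians of -0.68 and -0.78 on the log2 scale. HMGCS1, the enzyme that makes HMG-CoA, was 95.9 in untreated 1, 268 in untreated 2 and 267 in untreated 3, and 99.1, 202 and 303 in Tet-Express 1, 2 and 3. Of 26 p53 target genes 22 were higher in both comparisons (medians 0.58 and 0.55), with MDM2 at 365, 212 and 203 in the untreated libraries and GDF15 at 38.1, 8.45 and 7.69. Of 23 ribosome biogenesis and MYC target genes 22 were lower in both (medians -0.36 and -0.43). Of 17 primitive streak genes 7 were lower and 9 higher in both (medians 0.00 and 0.28), the lower ones including T at 39.7 in untreated 1 and 104 and 94.4 in untreated 2 and 3, and EOMES at 22.2, 52.2 and 53.9. No test was made of these differences. The deposited names of libraries 1 carry no number while those of the others do, but no label states what this means. With all 6 libraries the cholesterol synthesis, p53 target and ribosome biogenesis lists did not pass between treated and untreated (camera adjusted p = 0.736, 0.806 and 0.0785). Primitive streak genes did not pass either (0.723). Immediate early genes did pass at the preset correlation (adjusted p = 1.25e-07), but not with an estimated one (0.704). Ribosome biogenesis passed as higher with no filter on low values (0.0284) and with the batch term (0.0201), against an adjusted p = 0.841 with an estimated correlation. Without untreated 1, p53 targets passed as higher (0.00305) and cholesterol synthesis as lower (0.0365), and without Tet-Express 1 cholesterol synthesis passed as higher (0.00800). Each of these fits has a library numbered 1 in a single group. They therefore cannot tell treatment from the difference between libraries numbered 1 and others. With all libraries p53 targets and cholesterol synthesis each had an adjusted p = 0.968 with an estimated correlation.

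Liver transcripts were high in untreated libraries 2 and 3 alone. Hepatic differentiation is argued against, since AFP in these libraries was 0.961 times its mean elsewhere. A lowering by Tet-Express stays open, since untreated 1 had little to lower (a median of 0.0363 times the level of untreated 2 and 3 over 62 genes higher in both) and its median difference of 0 from Tet-Express 1 decides nothing. RNA or reads from liver stay open as a candidate source: 75.5% of 49 detected hepatocyte genes not looked at before (37) were higher in both libraries than in all others, against 8.09% of all genes (Fisher's exact p = 9.341e-31) and 0 of 9 liver transcription factors, which are less abundant. That p takes genes as independent, though they can move together, and does not measure variation between cultures. The bound set for other organs was missed because 1 of 4 detected blood genes (25%) was also higher, as was 1 of 8 muscle genes, and 1 shared source is not shown, as ratios of untreated 3 to untreated 2 over 33 liver genes ran from 0.951 (A2M) to 4.46 (ORM1), wider than counting error alone (chi-square 205, 32 degrees of freedom).

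Ribosomal protein and respiratory chain transcripts were higher in Tet-Express library 2. A change of this size shared by all treated cultures is argued against, since the ribosomal median was 0.15 in Tet-Express 3 and -0.01 in Tet-Express 1. Differences in this library correlated with transcript length across genes (r = -0.60, genes not being independent replicates). Removing that trend lowered the ribosomal median from 0.95 to 0.46 ± 0.04 (SE) and the respiratory chain median from 0.79 to 0.37. That SE is over the list's genes in this library and does not measure variation between cultures. The ribosomal genes moved together, with an estimated correlation of 0.90 over all libraries, so it may be too small. Length may thus account for part of the change, and more was left than a full account by length predicted. The amount left depended on the transcript chosen, with 0.60 left when the longest was used, so the test cannot exclude a larger share. Removing the trend on GC content left 0.91, and RNA quality and the state of this culture stay open, untested.

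Immediate early genes were higher in Tet-Express libraries 2 and 3 than in untreated 2 and 3, with Tet-Express 2 placed by its number alone. Tet-Express 1 showed no rise against untreated 1 (median -0.0319). Untreated 1 already exceeded untreated 2 and 3 by a median of 0.67, so this pair does not decide on a rise in every treated culture. In Tet-Express 3 differences had no trend on transcript length (r = -0.00740), and removing the trend on GC content moved the median from 0.56 to 0.58 ± 0.11 (SE over the list's genes). In Tet-Express 2 the median of 0.35 ± 0.16 became 0.33 ± 0.15 without the length trend and 0.13 ± 0.13 without the GC trend (SE over the list's genes). GC content may thus account for the higher values of that library. Variation between cultures met the prediction written for it after the result was seen. Untreated libraries were to differ by at least as much as Tet-Express 3, and the 0.67 of untreated 1 exceeds its 0.56. A further condition was then added, as untreated 1 lies outside the batch of Tet-Express 3, a batch no label gives. The 1 untreated pair within it differed by -0.00632 ± 0.0151 (SE over the list's genes). Variation between cultures therefore stays open, as does a response to Tet-Express, as a hypothesis.

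The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower, where the highest other split gave 768 in one direction, and as many or more genes came from all 10. A real count of 0 fixed that share in advance, so it decides nothing. In lists the real split gave 9, where the highest other gave 10 and 2 of the 10 splits gave at least as many. The split that set untreated 1, Tet-Express 1 and Tet-Express 2 against the rest called 1257 genes, which points to a structure of the samples other than treatment.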
